A study of Mus musculus with 11 samples.

How the data were processed

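RNA was sequenced from the right-eye retina of 11 mice at postnatal day 24, in 4 groups that cross genotype with treatment: wild-type C57Bl/6J mice and mice of the rd10 strain, which carries a mutant allele of Pde6b, each given daily intraperitoneal saline or the LSD1 inhibitor GSK2879552 (GSK below) from day 9 to day 24 at 4.2 mg/kg. There were 2 wild-type saline, 3 wild-type GSK, 3 rd10 saline and 3 rd10 GSK libraries, 1 per animal, and the animal is the unit of every n. The labels state that each retina was flash frozen, that RNA integrity numbers were above 7, and that polyA RNA from 200 ng of total RNA went into stranded mRNA libraries. The deposit labels the strains C57Bl/6J and B6.CXB1-Pde6brd10/Jrd10, so any sequence difference between those backgrounds travels with the genotype. Sex, litter, dissection date and the time from death to freezing are not given in the sources used here.

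The single deposited table holds raw read counts per gene made by the authors, for 37991 Ensembl genes in 11 libraries, all of which were used. According to the submitters' processing notes, base calls were converted with bcl2fastq, reads were aligned with HISAT2 2.1.0, genes were counted with HTSeq and edgeR was used downstream. The notes name the builds NCBIM37 and mm9. The HTSeq version, its strand setting and the gene annotation are not given in the sources used here, so counts of genes that overlap another gene on the opposite strand, and of near-identical gene copies, are uncertain. Gene names were taken from GENCODE release M21 by Ensembl identifier: 32919 identifiers had a name and 5072 did not, and the latter held 0.627% of all counts. Raw reads were not analysed here.

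Libraries held between 19657030 and 28053367 counts, and between 20121 and 21137 genes had at least 1 count. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 17099 genes, and scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. A negative binomial model with 1 coefficient per group was fitted to all 11 libraries with robust quasi-likelihood (QL) dispersions, and 6 comparisons were tested with the QL F-test: rd10 saline against wild-type saline, rd10 GSK against rd10 saline, wild-type GSK against wild-type saline, the genotype by treatment interaction, rd10 GSK against wild-type GSK, and rd10 GSK against wild-type saline. The p-values of each comparison were adjusted over all tested genes by Benjamini-Hochberg (BH), and a gene is said to have risen, fallen or changed where the adjusted p was under 0.05. The common biological coefficient of variation was 0.129. Fold changes are log2 with their standard error after the sign ±, and expression levels are group means of library-scaled counts (CPM, edgeR cpm) with their standard deviation after ±.

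In simulated data with the real group sizes and depths, 100 genes were changed 2-fold and 100 others 1.5-fold. Each gene had the dispersion estimated over all groups, while the spread within the real groups was unequal. The test recovered 67%, 78%, 65% and 56% of the 2-fold changes in the first 4 comparisons, and 52%, 44%, 39% and 24% of the 1.5-fold changes. Of the genes called there, between 5.00% and 11.1% had not been changed. A gene that did not pass is therefore not shown to be unchanged. This holds most for the wild-type and interaction comparisons, where the fewest 1.5-fold changes were recovered. Every comparison that uses wild-type saline rests on 2 animals of that group.

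Gene groups were 29 lists of retinal cell types, glial, immune, stress and metabolic genes and the LSD1 and HDAC complexes, together with tissues that a dissection could carry (lens, retinal pigment epithelium, blood, vessel, muscle), fixed before the data were examined. The lists hold 408 entries, of which 6 genes could not be matched (Lrit3, Slc18a3, C1s, Psmb9, Hbb-b1 and Hbb-b2). For each list it describes in a comparison, the text gives the members that rose and fell, the same count with p-values adjusted over the list alone, and the median log2 change. The 26 lists with at least 5 measured members were also tested with camera on voom values (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted by BH over the lists. Because members of a cell-type list vary together, camera was repeated with a correlation estimated per list, and that adjusted p is given beside each list whose call it ends. The rotation test fry, which does not set a list against other genes, was run as a further check, and is mentioned where it disagrees with the camera call. Camera sets a list against all other genes, so a list can pass while its own median is close to 0.

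Genes to be named were chosen by a rule written before the data were examined: Kdm1a, Hdac1 and Pde6b in every comparison; in each comparison the 10 rising and 10 falling genes with the largest changes among those that passed, had a mean of at least 5 CPM and showed no overlap between the libraries compared, skipping predicted and unnamed genes; and from each list up to 4 members that passed, or the 2 most highly expressed where none did. The libraries were not required to separate for the interaction. From the set so named the text prefers genes whose call held in every alternative setting; that preference was applied after the results were seen. A few genes that the rule names are not reported here. Of the named results that passed, 68 of 102 held in every setting for rd10 saline against wild-type saline, 48 of 102 for rd10 GSK against rd10 saline, 6 of 20 for wild-type GSK against wild-type saline, 20 of 58 for the interaction, 13 of 21 for rd10 GSK against wild-type GSK and 6 of 21 for rd10 GSK against wild-type saline.

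The alternatives fixed in advance were scaling on amacrine, bipolar and ganglion cell genes (inner retina scaling, minimum count 10), size factors by relative log expression, no low-count filter, a filter of 1 CPM in 3 libraries, replicate number as a block, each library left out in turn, fits of only the groups compared, limma-voom, and DESeq2 1.42.0. After the data were seen, 2 more were added: leaving out the 2 libraries that carried lens transcripts (wild-type saline replicate 2 and rd10 GSK replicate 2), and the level of Xist as a covariate. Whether replicates with the same number belong together was checked on the correlation of residuals over 15 pairs, which ran from -0.228 to 0.233 with 3 above 0.1, and the numbers were not treated as pairs. No 2 libraries of a group were copies of each other (chi-square per degree of freedom between 3.72 and 49.4 for genes with at least 20 counts). In the test of neighbouring genes, gene order came from the RefSeq table for GRCm38, which is a different build from that of the counts, and was matched by gene name.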

Results

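The first principal component of expression carried 61.0% of the variance and separated wild type from rd10 saline. On it the rd10 GSK libraries ran from 52.0, level with rd10 saline replicate 1 at 52.8, to -10.4. On the second component (12.6%) rd10 GSK replicates 1, 2 and 3 lay at -27.4, -43.8 and -26.6. All other libraries lay between -1.45 and 30.6 there. Transcripts of lens genes summed to 856 CPM in wild-type saline replicate 2 and 8632 CPM in rd10 GSK replicate 2, against at most 129 CPM in the other 9 libraries. Xist, expressed from the inactive X chromosome of females, was at 0.338 CPM or less in wild-type GSK replicate 2, rd10 saline replicate 2 and rd10 GSK replicates 1 and 3. It was at 780 CPM or more in the other 7 libraries. All wild-type saline libraries were among these, but only replicate 2 of rd10 GSK, so the level of Xist was unbalanced over the groups.

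Kdm1a, which encodes LSD1, stood at 95.5 ± 0.583 CPM in wild-type saline, 100 ± 4.01 in wild-type GSK, 86.2 ± 2.83 in rd10 saline and 97.4 ± 5.69 in rd10 GSK. It was not called between the saline groups (log2 fold change -0.15 ± 0.06, edgeR adjusted p = 0.0725) or between the wild-type groups (0.07 ± 0.06, adjusted p = 0.865). It rose slightly with GSK in rd10 (0.18 ± 0.06, edgeR adjusted p = 0.0281), a call lost without the lens-bearing libraries, without replicate 3 of either rd10 group, and when only the compared groups were fitted. Hdac1, a histone deacetylase of the same corepressor complexes, was at 36.8 ± 1.10, 36.7 ± 0.722, 44.0 ± 0.927 and 36.7 ± 3.67 CPM in the same order. It was higher in rd10 saline than in wild-type saline (0.26 ± 0.08, edgeR adjusted p = 0.0198) and lower in rd10 GSK than in rd10 saline (-0.26 ± 0.07, adjusted p = 0.0123). Both calls were lost without the lens-bearing libraries and under inner retina scaling, where the latter change became 0.058. Pde6b, the rod phosphodiesterase subunit mutated in rd10, went from 2266 ± 49.8 CPM in wild-type saline to 362 ± 51.9 in rd10 saline (-2.64 ± 0.20, edgeR adjusted p = 1.07e-05). In rd10 GSK it was at 1376 ± 383 CPM (1.93 ± 0.18 against rd10 saline, adjusted p = 6.97e-05), and in wild-type GSK at 2243 ± 35.4 CPM (-0.01 ± 0.20, adjusted p = 0.997).

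In rd10 retinas given saline (n = 3) rod transcripts fell far below those of wild-type saline (n = 2). Guca1b, an activator of the guanylate cyclase that restores cGMP after light, went from 1196 ± 42.4 to 140 ± 15.5 CPM (log2 fold change -3.09 ± 0.16, edgeR adjusted p = 7.07e-07). Nrl, the transcription factor that specifies rods, fell by 2.96 ± 0.29 on the log2 scale and Gnat1, the rod transducin subunit, by 2.81 ± 0.22. All 16 measured rod genes fell (16 adjusted over the list alone, median -2.65). The rod list had camera adjusted p = 3.19e-15 (adjusted p = 0.306 with an estimated correlation). Of 24 genes that rods share with cones 23 fell (24 adjusted over the list alone, median -1.87), with camera adjusted p = 3.04e-18 (adjusted p = 0.306 with an estimated correlation). Among them were Pdc, the phosducin that binds transducin (-2.87 ± 0.29), and Prph2, a structural protein of the outer segment discs (-2.59 ± 0.19). Outside the lists the largest falls included Pdzph1 (-3.93 ± 0.18, adjusted p = 7.02e-07) and Nxnl1, which encodes the rod-derived cone viability factor (-2.95 ± 0.22).

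The 14 measured cone genes had no common direction in rd10 saline (1 rose and 2 fell, the same adjusted over the list alone, median -0.09, camera adjusted p = 0.190). Gnb3, a cone transducin subunit, rose (1.02 ± 0.19, edgeR adjusted p = 0.00218), while Thrb, the thyroid hormone receptor of cone differentiation, fell (-0.68 ± 0.10, adjusted p = 0.000423). Of 14 bipolar genes 8 rose (8 adjusted over the list alone, median 0.25), with adjusted p = 0.00977 (adjusted p = 0.306 with an estimated correlation). Grik1, a kainate receptor subunit (0.56 ± 0.10), and Trpm1, the ON bipolar cation channel (0.45 ± 0.09), were among them. Amacrine genes passed no list test (1 of 9 rose, 0 adjusted over the list alone, median 0.10, adjusted p = 0.494). Ganglion cell genes (3 of 11 fell, 3 adjusted over the list alone, median -0.14) had camera adjusted p = 0.123, but 0.0470 without the lens-bearing libraries, and fry adjusted p = 0.0422. The neurofilament gene Nefh was 1 of those that fell (-0.43 ± 0.05, adjusted p = 0.000107). Of 4 horizontal cell genes 1 rose (2 adjusted over the list alone, median 0.09).

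Glial and immune transcripts rose in rd10 saline. All 16 reactive gliosis genes rose (16 adjusted over the list alone, median 3.57), with camera adjusted p = 2.97e-07 (adjusted p = 0.325 with an estimated correlation). The acute-phase serpin Serpina3n went from 4.50 ± 0.468 to 303 ± 43.0 CPM (6.07 ± 0.69, edgeR adjusted p = 0.000378). Edn2, an endothelin gene induced in stressed photoreceptors, went from 1.05 to 36.6 ± 4.66 CPM (5.11 ± 0.56). Of 10 Müller glia genes 7 rose (7 adjusted over the list alone, median 0.77), with adjusted p = 0.000204 (adjusted p = 0.112 with an estimated correlation). They included the lipid carrier Apoe (1.92 ± 0.14, edgeR adjusted p = 3.93e-06) and the water channel Aqp4 (0.97 ± 0.09). All 17 microglia genes rose (17 adjusted over the list alone, median 3.30), with adjusted p = 8.20e-10 (adjusted p = 0.320 with an estimated correlation). So did all 14 microglial activation genes (14 adjusted over the list alone, median 4.31), with adjusted p = 0.000113 (adjusted p = 0.325 with an estimated correlation). The complement initiator C1qc went from 5.88 ± 0.421 to 80.7 ± 8.56 CPM (3.78 ± 0.32), and the signalling adaptor Tyrobp from 1.40 ± 0.0124 to 20.9 ± 1.80 CPM (3.90 ± 0.54).

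All 18 interferon response genes rose as well (18 adjusted over the list alone, median 4.04), with adjusted p = 7.71e-07 (adjusted p = 0.325 with an estimated correlation). The interferon-induced Usp18 (5.96 ± 0.98) and Ifit1 (5.80 ± 1.02) were among its largest rises, but neither was called by limma-voom. All 8 genes of MHC class I presentation rose (8 adjusted over the list alone, median 3.65), with adjusted p = 7.60e-05 (adjusted p = 0.325 with an estimated correlation), the light chain B2m by 4.08 ± 0.65. Of 9 complement genes 8 rose (8 adjusted over the list alone, median 4.09), with adjusted p = 0.000113 (adjusted p = 0.325 with an estimated correlation), and C4b rose by 5.40 ± 0.38 (edgeR adjusted p = 2.09e-05). Of 17 inflammatory mediators 9 rose (12 adjusted over the list alone, median 3.80), with adjusted p = 0.00158 (adjusted p = 0.462 with an estimated correlation and 0.0650 by fry). The inflammasome caspase Casp1 was 1 of them (5.46 ± 0.93, at 3.26 ± 0.293 CPM in rd10 saline). Of 3 other leukocyte genes 1 rose (1 adjusted over the list alone, median 0.61). This was Gzmb, a cytotoxic granule protease, at only 0.022 and 0.507 CPM, and its call was lost without wild-type saline replicate 1 and without the lens-bearing libraries.

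Death, division and stress genes also moved. Of 20 cell death genes 13 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.61), with camera adjusted p = 0.00104 (adjusted p = 0.325 with an estimated correlation), and the death receptor Fas rose by 2.46 ± 0.47. Of 12 proliferation genes 10 rose (10 adjusted over the list alone, median 2.33), with adjusted p = 0.00206 (adjusted p = 0.325 with an estimated correlation). The cycling marker Mki67 went from 0.114 ± 0.0255 to 9.57 ± 2.36 CPM. Of 17 neurotrophic and protective genes 11 rose and 1 fell (the same adjusted over the list alone, median 0.61), with adjusted p = 0.00158 (adjusted p = 0.306 with an estimated correlation). The metallothionein Mt2 rose by 3.12 ± 0.26 (edgeR adjusted p = 3.08e-05) and the growth factor Fgf2 by 2.54 ± 0.44 (adjusted p = 0.00231). Of 12 immediate-early genes 6 rose (8 adjusted over the list alone, median 0.72), with adjusted p = 0.00564 (adjusted p = 0.325 with an estimated correlation), such as the transcription factor Egr1 (2.26 ± 0.31). Retinal progenitor genes (4 of 12 rose and 1 fell, 6 and 1 adjusted over the list alone, median 0.54) had camera adjusted p = 0.0604 and fry adjusted p = 0.00418. Camera called them in 6 of 20 settings, among them without wild-type saline replicate 1 (adjusted p = 0.0457), rd10 saline replicate 3 (0.0338) or rd10 GSK replicate 1 (0.0369). Of 16 genes of the LSD1 and HDAC complexes 2 rose and 5 fell (the same adjusted over the list alone, median -0.14, camera adjusted p = 0.239, fry adjusted p = 0.0298), with the silencing factor Rest up by 0.58 ± 0.09.

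Energy metabolism genes were lower. Of 18 oxidative phosphorylation genes 9 fell (10 adjusted over the list alone, median -0.18, and -0.28 without rd10 saline replicate 2), with adjusted p = 0.000306 (adjusted p = 0.426 with an estimated correlation) and Ndufa4 at -0.73 ± 0.10. Of 19 glycolysis genes 11 fell (12 adjusted over the list alone, median -0.25), with adjusted p = 0.000759 (adjusted p = 0.325 with an estimated correlation). The hexokinase Hk2 (-1.65 ± 0.23, edgeR adjusted p = 0.000512) and the lactate transporter Slc16a1 (-1.32 ± 0.21) were among them. Of the tissues that a dissection can carry, all 6 erythroid genes fell (6 adjusted over the list alone, median -1.74), with adjusted p = 0.00154 (adjusted p = 0.306 with an estimated correlation). The haem synthesis enzyme Alas2 fell by 1.83 ± 0.29 on the log2 scale. Vascular genes passed no list test (3 of 11 rose and 1 fell, the same adjusted over the list alone, median -0.06 with camera pointing up, adjusted p = 0.695), but the VEGF receptor Kdr rose (1.17 ± 0.14). None of 12 pigment epithelium genes (median -0.33, adjusted p = 0.507), 4 skeletal muscle genes (median -0.79) or 15 lens genes changed, and none did adjusted over the list alone. The pigment epithelium median ran from -0.79 to 0.33 over the settings. The lens median of -5.86 was set by wild-type saline replicate 2 (adjusted p = 0.447).

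**Figure D1:**
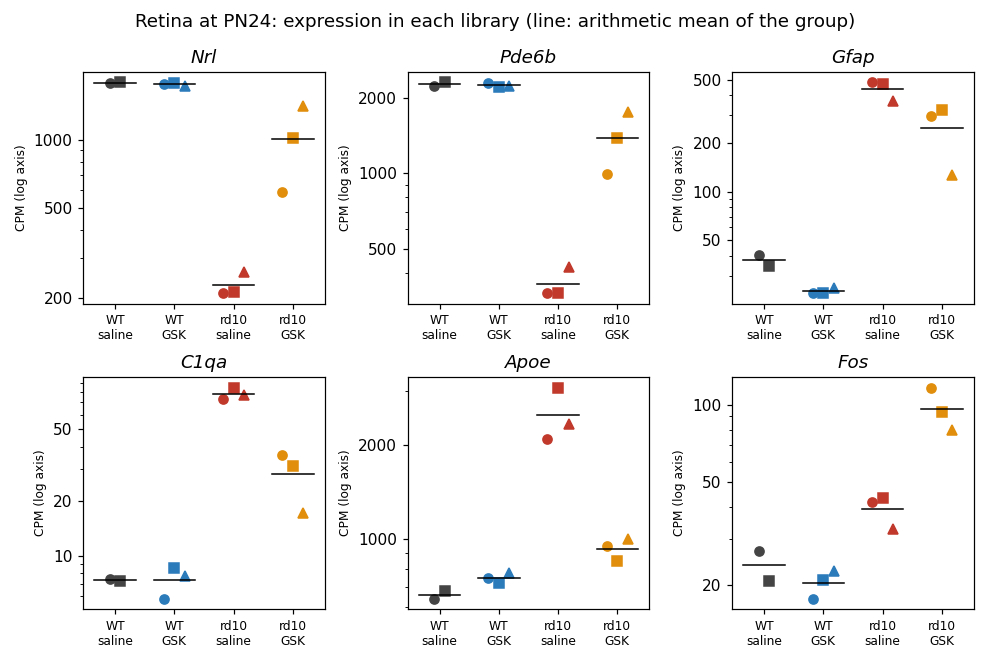
Expression in CPM (log axis) of Nrl, Pde6b, Gfap, C1qa, Apoe and Fos in each of the 11 libraries by group, with a line at the arithmetic mean of the group and marker shapes for replicate numbers. Nrl averages 1784 CPM in wild-type saline, 228 CPM in rd10 saline and 1002 CPM in rd10 GSK.

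Over all genes, 6919 of 17099 differed between rd10 saline and wild-type saline, 3669 higher and 3250 lower in rd10 (edgeR QL, BH adjusted p under 0.05). By 2-fold or more, 1475 were higher and 620 lower. The count depends on the 2 wild-type saline animals: it was 4435 without replicate 1, 4441 without replicate 2 and 4081 without the lens-bearing libraries. The share of called genes that were higher was 53.0%, and 43.7% under inner retina scaling.

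Photoreceptor transcripts were higher in rd10 retinas given GSK than in those given saline (n = 3 in each group). Counts are relative within a whole retina. They cannot tell a changed number of cells of a type from changed expression per cell, for this or any other list. Guca1b stood at 672 ± 151 CPM in rd10 GSK (2.26 ± 0.14 against rd10 saline, edgeR adjusted p = 4.50e-06). Nrl rose by 2.13 ± 0.27 and Esrrb, an orphan receptor of rod energy metabolism, by 2.18 ± 0.22. All 16 rod genes rose (16 adjusted over the list alone, median 1.81), with camera adjusted p = 1.41e-13 (adjusted p = 0.301 with an estimated correlation). All 24 genes shared by rods and cones rose (24 adjusted over the list alone, median 1.38), with adjusted p = 9.68e-18 (adjusted p = 0.275 with an estimated correlation), Prph2 by 1.88 ± 0.18. As a percentage of the wild-type saline mean, the rod list stood at 40.8%, 59.7% and 77.4% in rd10 GSK replicates 1, 2 and 3, against 16.3%, 16.3% and 19.7% in rd10 saline. Outside the lists Pdzph1 rose by 3.01 ± 0.16 (edgeR adjusted p = 3.09e-06), the voltage-gated sodium channel Scn4a by 2.88 ± 0.54, and the nuclear envelope protein Syne3 by 2.20 ± 0.22.

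Genes of bipolar cells and of Müller glia fell. Of 14 bipolar genes 12 fell (13 adjusted over the list alone, median -0.47, and -0.16 under inner retina scaling), with adjusted p = 2.25e-08 (adjusted p = 0.0171 with an estimated correlation). The calcium-binding protein Cabp5 (-0.70 ± 0.05, edgeR adjusted p = 7.31e-06) and the homeobox factor Isl1 (-0.66 ± 0.05) were examples. With TMM scaling the bipolar list stood at 80.5%, 83.8% and 88.5% of wild-type saline in rd10 GSK replicates 1, 2 and 3. It stood at 116%, 116% and 117% in rd10 saline, so it passed below the wild-type level. Inner retina scaling is set on amacrine, bipolar and ganglion cell genes, so it centres them near 0 by construction and is no independent check on these 3 lists. Of 10 Müller glia genes 8 fell (9 adjusted over the list alone, median -0.60, and -0.29 under inner retina scaling), with adjusted p = 7.16e-07 (adjusted p = 0.0171 with an estimated correlation). Apoe went from 2504 ± 504 to 929 ± 75.9 CPM (-1.43 ± 0.12, edgeR adjusted p = 1.62e-05). Aqp4 fell by 1.01 ± 0.08 and Rlbp1, a retinoid-binding protein of the visual cycle, by 0.87 ± 0.14 on the log2 scale. The Müller glia list stood at 92.0%, 96.7% and 107% of wild-type saline in rd10 GSK, against 172%, 173% and 165% in rd10 saline.

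Of 11 ganglion cell genes 9 fell (10 adjusted over the list alone, median -0.29, but 0.02 under inner retina scaling), with adjusted p = 2.89e-05 (adjusted p = 0.275 with an estimated correlation). With TMM scaling the ganglion cell list stood at 69.9%, 76.2% and 80.2% of wild-type saline in rd10 GSK replicates 1, 2 and 3. That was further below wild type than the 93.0%, 91.8% and 90.1% in rd10 saline. Of 9 amacrine genes 1 rose and 4 fell (1 and 6 adjusted over the list alone, median -0.18, but 0.13 under inner retina scaling). The amacrine list had adjusted p = 0.0306 (adjusted p = 0.396 with an estimated correlation), a call also lost without rd10 GSK replicate 1 (0.0973) and with only the compared groups fitted (0.0503). Of 4 horizontal cell genes 2 fell (2 adjusted over the list alone, median -0.44), with the developmental factor Lhx1 at -0.73 ± 0.09. Cone genes (1 of 14 rose and 5 fell, the same adjusted over the list alone, median -0.18) had camera adjusted p = 0.0686. Camera called them in 5 of 20 settings, among them without rd10 GSK replicate 2 (median -0.29, adjusted p = 0.0299), without replicate 3 (-0.29, 0.0101) and under inner retina scaling (0.14, 0.0201). Camera pointed down in each, and under that scaling the median of all genes was 0.32. Thrb rose (0.43 ± 0.10) and Ccdc136 fell (-0.58 ± 0.10).

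Microglial transcripts were lower with GSK in rd10 but above the wild-type saline mean in each library. Of 17 microglia genes 14 fell (17 adjusted over the list alone, median -1.36), with camera adjusted p = 1.53e-09 (adjusted p = 0.334 with an estimated correlation). The lipid receptor Trem2 fell by 1.83 ± 0.22 on the log2 scale (edgeR adjusted p = 0.000138), C1qc by 1.56 ± 0.24 and C1qa by 1.47 ± 0.24. The list stood at 455%, 289% and 178% of wild-type saline in rd10 GSK replicates 1, 2 and 3, and at 682%, 809% and 865% in rd10 saline. Of 14 microglial activation genes 6 fell (6 adjusted over the list alone, median -1.55, and -2.44 without rd10 GSK replicate 1), with adjusted p = 3.65e-05 (adjusted p = 0.403 with an estimated correlation). The class II antigens H2-Aa (-2.69 ± 0.73) and H2-Eb1 (-2.66 ± 0.65) were among them, but not without rd10 GSK replicate 3. Of 9 complement genes 4 fell (7 adjusted over the list alone, median -1.14), with adjusted p = 0.000675 (adjusted p = 0.403 with an estimated correlation), C4b by 1.55 ± 0.26. Interferon response (2 of 18 fell, 0 adjusted over the list alone, median -0.96) had adjusted p = 3.92e-05 (adjusted p = 0.545 with an estimated correlation and 0.0674 by fry). It stood at 1117%, 939% and 233% of wild-type saline in rd10 GSK replicates 1, 2 and 3, against 1360%, 1593% and 1573% in rd10 saline. Its median change was -0.53 without replicate 3 of rd10 GSK and -0.62 under inner retina scaling. MHC class I (3 of 8 fell, 3 adjusted over the list alone, median -0.95) had adjusted p = 0.00143 (adjusted p = 0.480 with an estimated correlation), and a median of -0.61 both without that library and under that scaling.

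Reactive gliosis genes had no stable direction with GSK in rd10 (1 of 16 rose, 1 adjusted over the list alone, median -0.37, camera adjusted p = 0.358). The list was called without rd10 GSK replicate 1 (median -0.88, adjusted p = 0.0126) and under inner retina scaling (-0.022, 0.000967), with camera pointing down in both, and its median was 0.066 without replicate 3. The list stood at 1816%, 1164% and 456% of wild-type saline in rd10 GSK replicates 1, 2 and 3, against 1440%, 1305% and 1296% in rd10 saline. The member that rose, the inflammatory transcription factor Cebpd, went from 72.3 ± 9.50 to 177 ± 74.3 CPM (1.30 ± 0.30, edgeR adjusted p = 0.0118). Inflammatory mediators (1 of 17 rose, 0 adjusted over the list alone) had a median of 0.56 while camera pointed down (adjusted p = 0.468). The median was -0.20 without rd10 GSK replicate 1 (adjusted p = 0.0238), 0.87 without replicate 3, where camera pointed up (0.0345). Under inner retina scaling it was 0.89 with camera pointing down (0.000750). Proliferation genes (2 of 12 rose and 2 fell, the same adjusted over the list alone, median -0.94) had camera adjusted p = 0.0528. They were called without rd10 GSK replicate 2 (median -1.39, adjusted p = 0.00357), without the lens-bearing libraries (0.00392), without a low-count filter (0.0227) and under inner retina scaling (-0.61, 0.000205), and their median was -0.52 without rd10 GSK replicate 3. Cell death genes passed no list test (2 of 20 rose and 1 fell, 1 and 1 adjusted over the list alone, median -0.07, adjusted p = 0.542). Progenitor genes (2 of 12 rose and 2 fell, the same adjusted over the list alone) had a median of 0.05 with camera pointing down (adjusted p = 0.931). Cdkn1a, the p53-induced cell cycle inhibitor, rose by 1.05 ± 0.11 (edgeR adjusted p = 6.00e-05).

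**Figure D2:**
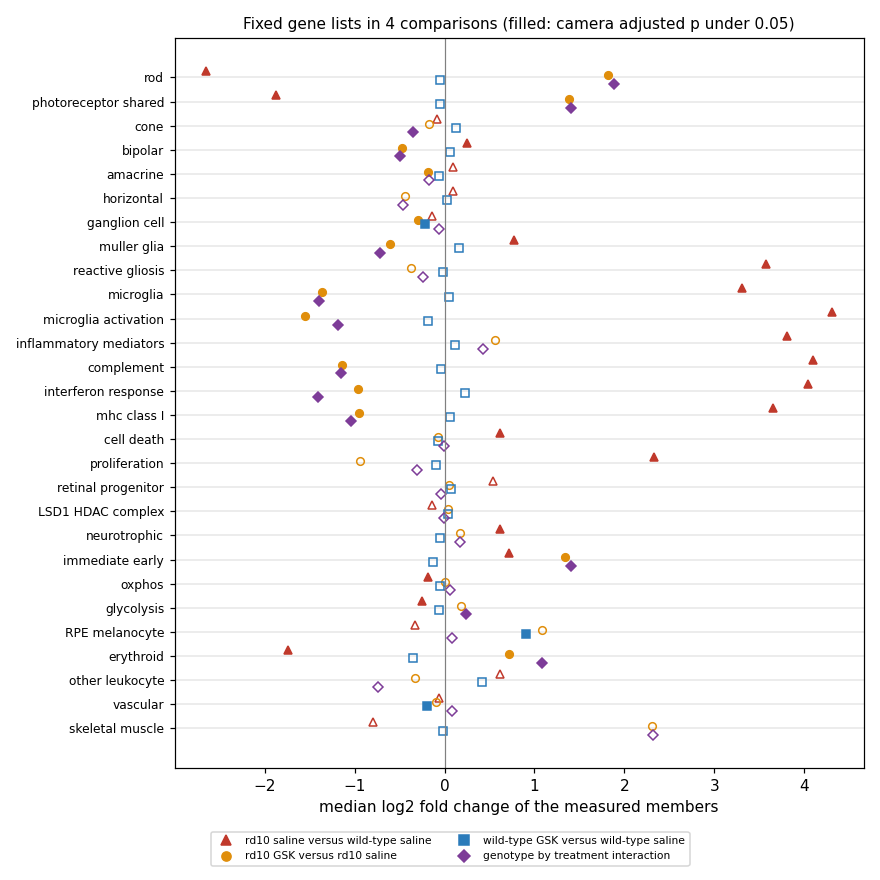
Median log2 fold change of each of 28 gene lists (the lens list is left out) in 4 comparisons, with filled markers where the camera adjusted p at the preset correlation is under 0.05; the horizontal cell, other leukocyte and skeletal muscle lists have too few measured members for that test and stay open. The rod list lies at -2.65 for rd10 saline against wild-type saline, at 1.81 for rd10 GSK against rd10 saline and at -0.05 for wild-type GSK against wild-type saline.

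Immediate-early genes were highest in rd10 GSK, and the labels give no time from death to freezing. Of 12 members 10 rose with GSK in rd10 (11 adjusted over the list alone, median 1.34), with camera adjusted p = 2.42e-07 (adjusted p = 0.270 with an estimated correlation). The nuclear receptor Nr4a1 went from 43.4 ± 3.95 to 131 ± 6.01 CPM (1.59 ± 0.07, edgeR adjusted p = 4.15e-07), and the AP-1 subunit Junb (1.72 ± 0.26) and the activity-induced factor Npas4 (1.68 ± 0.21) rose too. Glycolysis genes moved in both directions (9 of 19 rose and 3 fell, the same adjusted over the list alone, median 0.19, camera adjusted p = 0.0633, fry adjusted p = 0.0272). Camera called them in 5 of 20 settings, among them without rd10 saline replicate 2 (adjusted p = 0.0376) and without rd10 GSK replicate 1 (0.0176). Another was inner retina scaling (median 0.50, adjusted p = 0.00727). Hk2 went from 131 ± 20.4 to 538 ± 159 CPM (2.04 ± 0.21, edgeR adjusted p = 0.000179) and Hk1 rose by 0.83 ± 0.06. Oxidative phosphorylation genes (3 of 18 rose, 2 adjusted over the list alone, median 0.01) had adjusted p = 0.454, but 0.00699 without rd10 saline replicate 2 and 0.00186 under inner retina scaling. Neurotrophic genes passed no list test (2 of 17 rose and 1 fell, the same adjusted over the list alone, median 0.17, adjusted p = 0.519). Of the LSD1 and HDAC complexes 6 of 16 genes rose and 1 fell (6 and 2 adjusted over the list alone, median 0.04), with camera adjusted p = 0.320, but 0.0201 under inner retina scaling, and fry adjusted p = 0.0272. Rcor3, a corepressor partner of LSD1, rose by 0.39 ± 0.07.

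Among non-retinal tissues, 3 of 6 erythroid genes rose with GSK in rd10 (3 adjusted over the list alone, median 0.72), Alas2 by 1.31 ± 0.27. The erythroid list had adjusted p = 0.0416 (adjusted p = 0.403 with an estimated correlation), a call lost in 6 of 20 settings. Among these were leaving out rd10 saline replicate 1 (adjusted p = 0.0559), 2 (0.0522) or 3 (0.0908) and rd10 GSK replicate 1 (0.124). Vascular genes (1 of 11 rose and 3 fell, 1 and 4 adjusted over the list alone, median -0.09) had camera adjusted p = 0.121 and fry adjusted p = 0.00519. Kdr fell from 607 ± 50.2 to 309 ± 43.8 CPM (-0.97 ± 0.12, edgeR adjusted p = 0.000183). Pigment epithelium genes (1 of 12 fell, 1 adjusted over the list alone) had a median of 1.08 (adjusted p = 0.299), and from 0.48 to 1.48 over the settings. The lens list (1 of 15 rose, 0 adjusted over the list alone) had a median of 6.75, set by rd10 GSK replicate 2 (adjusted p = 0.468). Of 3 other leukocyte genes 1 fell (1 adjusted over the list alone, median -0.33). Of 4 skeletal muscle genes 1 rose (4 adjusted over the list alone, median 2.30), and rd10 GSK replicate 3 carried most of it. The list summed to 36.5 CPM there, against 5.82 and 6.78 CPM in replicates 1 and 2 and at most 4.57 CPM in rd10 saline. The gene that rose, the actin Acta1, changed by 1.67 ± 0.49, and by 0.76 without that library. Its call was lost in 8 of 21 settings, among them without rd10 saline replicate 1 (adjusted p = 0.0627), 2 (0.0644) or 3 (0.0870).

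In all, 5621 genes changed with GSK in rd10, 3014 upward and 2607 downward (edgeR QL, BH adjusted p under 0.05), of which 553 and 270 by 2-fold or more. Fitted without the wild-type groups the count was 3588. Under inner retina scaling, which moved the median of all genes by 0.32, it was 9073, with 95.1% higher in place of 53.6%.

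**Figure D3:**
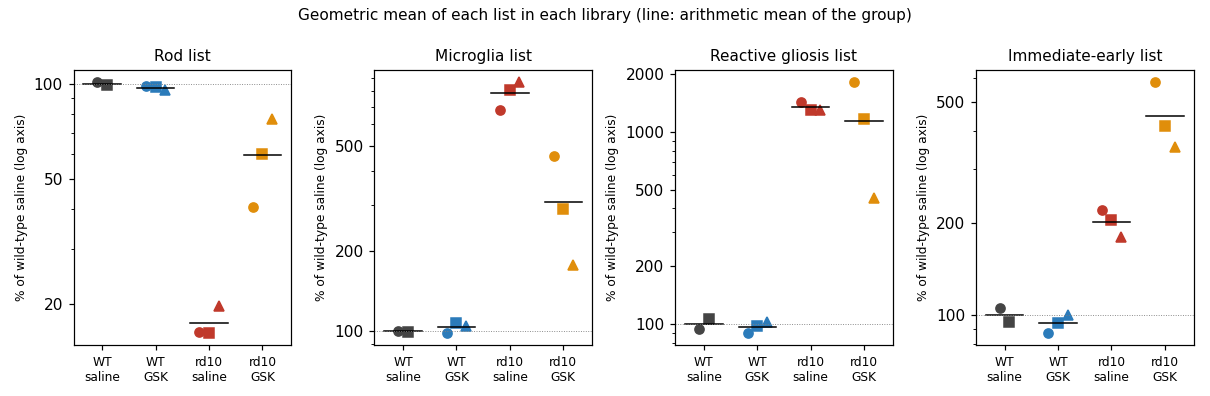
Geometric mean expression of the rod, microglia, reactive gliosis and immediate-early lists in each of the 11 libraries as a percentage of the wild-type saline mean (log axis), by group, with a line at the arithmetic mean of the group and marker shapes for replicate numbers. In rd10 GSK the rod list ranges from 40.8% to 77.4% and the reactive gliosis list from 456% to 1816%.

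For most genes called between the saline groups the shift with GSK ran opposite to the shift in rd10. Of the 6919 genes that differed between the saline groups, 6093 (88.1%) moved the other way with GSK in rd10. Of the 3657 called in both comparisons 3540 (96.8%) did so. Both comparisons use the same rd10 saline libraries, which by itself makes signs oppose. In simulated data with the real rd10 difference and no treatment effect the share was 57.6% (mean of 10 draws, highest 59.0%). These draws vary each gene independently, while members of a list moved together (estimated correlation 0.93 for rod genes between the saline groups). Their narrow range therefore does not show how far the share can vary by chance. The covariance of the log2 changes across all tested genes was -0.336, and -0.0411 in those simulations. The lens genes are among them, with medians of -5.86 and 6.75 in these comparisons, each set by 1 library. With 3 rd10 saline libraries the controls could not be divided into separate sets of at least 2. Among genes lower in rd10, 2008 rose and 19 fell with GSK, and among those higher in rd10, 1532 fell and 98 rose.

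**Figure D4:**
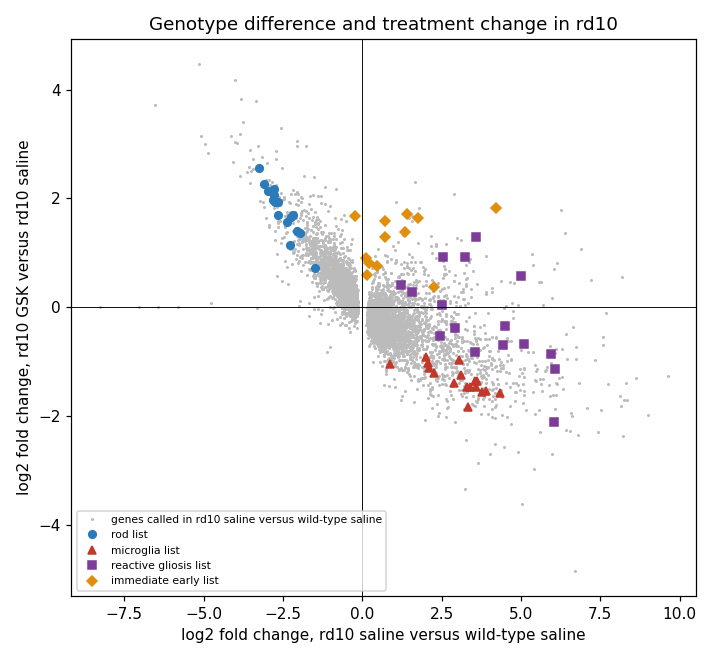
Log2 fold change of rd10 saline against wild-type saline (horizontal axis) and of rd10 GSK against rd10 saline (vertical axis) for the 6919 genes called in the former, with all measured members of the rod, microglia, reactive gliosis and immediate-early lists in colour, called or not. Of the 6919 genes 88.1% have opposite signs, against 57.6% in simulations that share the rd10 saline libraries, draw each gene independently and have no treatment effect.

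On the log2 scale the difference from wild type was reduced to unequal degrees. Against wild-type saline, rd10 GSK retinas differed in 4180 genes, 2416 higher and 1764 lower, and 2788 (40.3%) of the 6919 genes of the saline comparison were still called. For the 620 genes lower by 2-fold or more in rd10 saline, the median share of the log2 difference removed was 67.0% and 284 (45.8%) were still called. For the 1475 genes higher by 2-fold or more it was 25.8%, with 1038 (70.4%) still called. These shares were measured on the libraries that also defined the genes. For the same linear return a share of a log2 difference is larger for genes lower in rd10 than for genes higher in rd10. The 2 directions were not compared on the linear scale. Nxnl1 remained lower (-1.47 ± 0.22, edgeR adjusted p = 0.00238), as did the nuclear envelope gene Sun2 (-1.84 ± 0.08, adjusted p = 2.60e-07). Cebpd (4.88 ± 0.44) and Lad1, an epithelial anchoring protein (4.97 ± 0.41), remained higher. Both lay further from wild-type saline in rd10 GSK than in rd10 saline. Pde6b was lower by this test (-0.72 ± 0.19, adjusted p = 0.0250), a call lost in several settings. The count was 1053 without wild-type saline replicate 1, 1615 without replicate 2, 726 without the lens-bearing libraries and 1573 when only these groups were fitted. Under inner retina scaling it was 7397, with 95.3% higher against 57.8%. With Xist as a covariate 2956 genes were called, 2752 of them also without it.

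Compared with wild-type GSK, rd10 GSK retinas differed in 4484 genes, 2625 higher and 1859 lower. Edn2 (6.10 ± 0.55, edgeR adjusted p = 0.000333), Lad1 (5.77 ± 0.37), Serpina3n (5.62 ± 0.59) and Cebpd (4.63 ± 0.36) were higher. Sun2 was at 33.7 CPM in wild-type GSK, 9.47 CPM in rd10 GSK (-1.83 ± 0.07, adjusted p = 1.31e-07) and 8.75 CPM in rd10 saline, and the strain labels of the genotypes differ. The chemokine gene Ccl27a, which has near-identical copies in the mouse genome, was at 10.9 CPM in wild-type GSK and 0.395 CPM in rd10 GSK. Pde6b was lower as well (-0.70 ± 0.18, adjusted p = 0.0175), but not without wild-type GSK replicate 1 or without the lens-bearing libraries. The count was 2515, 2654 and 2914 without wild-type GSK replicates 1, 2 and 3, and 2213 without the lens-bearing libraries. Under inner retina scaling it was 5841, with 90.2% higher against 58.5%.

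In wild-type retinas few genes passed with GSK in the fit of all groups (n = 3 against 2). Hap1, a partner of huntingtin in vesicle transport, rose from 183 ± 13.5 to 424 ± 7.94 CPM (1.21 ± 0.07, edgeR adjusted p = 1.54e-05). Baiap3, a regulator of dense-core vesicle traffic, rose from 18.2 ± 0.709 to 59.1 ± 2.90 CPM (1.70 ± 0.11, adjusted p = 2.37e-05). Zcchc12, a zinc-finger coactivator of neurons, rose from 13.2 ± 0.576 to 37.7 ± 1.26 CPM (1.51 ± 0.10). Mal2, a membrane traffic protein, also rose (1.20 ± 0.09). The heavy neurofilament gene Nefh fell from 194 ± 4.54 to 127 ± 5.24 CPM (-0.61 ± 0.05, adjusted p = 0.000344). The calls of these 5 genes held in every setting. The synaptic vesicle gene Vamp1 (-0.47 ± 0.06), the calcium sensor Doc2a (1.62 ± 0.19) and the middle neurofilament gene Nefm (-0.41 ± 0.05) passed, but not when either wild-type saline library was left out.

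Ganglion cell genes were lower with GSK in wild type (2 of 11 fell, 6 adjusted over the list alone, median -0.21, and -0.12 under inner retina scaling), with camera adjusted p = 3.37e-09 (adjusted p = 0.169 with an estimated correlation). Pigment epithelium genes were higher as a list (0 of 12 rose, 1 adjusted over the list alone, median 0.90), with adjusted p = 1.16e-05 (adjusted p = 0.169 with an estimated correlation and 0.102 by fry). The median was 0.43 without wild-type saline replicate 1 and 1.64 without replicate 2. They stood at 172%, 179% and 240% of the wild-type saline mean in wild-type GSK replicates 1, 2 and 3, and at 70.2% and 142% in the wild-type saline libraries themselves. Vascular genes had a median of -0.20 (0 of 11 called, 1 up and 2 down adjusted over the list alone). The vascular list had adjusted p = 0.00755 (adjusted p = 0.169 with an estimated correlation and 0.0958 by fry), a call lost without the lens-bearing libraries (median -0.081, 0.295) and without wild-type saline replicate 2 (-0.084, 0.262). Under inner retina scaling its median was -0.11. Gnat1 was at 11676 ± 372 CPM in wild-type GSK (-0.18 ± 0.22, edgeR adjusted p = 0.942). No member was called, over all genes or adjusted over the list alone, among rod genes (median -0.05, adjusted p = 0.667) or genes shared by rods and cones (-0.05, adjusted p = 0.681). The same held for cone (0.12, adjusted p = 0.123), bipolar (0.07, adjusted p = 0.248), Müller glia (0.16, adjusted p = 0.0736) and immediate-early genes (-0.13, adjusted p = 0.667). With only the wild-type groups fitted, camera called the rod (adjusted p = 0.0394), cone (0.000445) and Müller glia lists (2.93e-05). With the replicate block it called the rod list as well (median -0.14, adjusted p = 0.0492). It also called the cone and Müller glia lists without rd10 GSK replicate 1 (0.0117 and 0.0276) or 3 (0.0467 and 0.0408). The Müller glia list was called as well without rd10 saline replicate 2 (0.0377) and without a low-count filter (0.0454). Bipolar genes were called under inner retina scaling (0.0274). In the remaining 20 lists no member passed over all genes, and adjusted over the list alone 1 rose in cell death and 1 in other leukocytes. The lens median was -6.88 (camera adjusted p = 0.123), and 0.88 without wild-type saline replicate 2. The other 19 medians lay between -0.35 (erythroid) and 0.42 (other leukocytes).

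Camera's calls on some of these lists in wild type changed with the setting. Erythroid genes (adjusted p = 0.0734) were called in 7 of 20 settings, among them without wild-type GSK replicate 1 (0.0119) or 3 (0.0392) and without rd10 GSK replicate 1 (0.0227) or 3 (0.0445). Glycolysis genes (median -0.06, adjusted p = 0.0734) were called in 6 of 20, among them with the replicate block (0.0249) and without wild-type saline replicate 2 (0.00586) or wild-type GSK replicate 3 (0.00273). The lens list was called in 5 of 20, among them with the replicate block (2.34e-12), without wild-type saline replicate 1 (4.40e-09) and without rd10 GSK replicate 2 (0.0120). Interferon response (median 0.23, adjusted p = 0.654) was called without rd10 GSK replicate 3 (0.0445), and oxidative phosphorylation (-0.05, adjusted p = 0.221) with Xist as a covariate (0.0269).

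Over all genes 91 changed in wild type, 76 upward and 15 downward (edgeR QL, BH adjusted p under 0.05), with 1535 at an unadjusted p under 0.05. The number is not fixed by these data. It was 12 without wild-type saline replicate 1, 17 without replicate 2, and 25, 25 and 27 without wild-type GSK replicates 1, 2 and 3. It was 182 without rd10 GSK replicate 1, 149 without rd10 GSK replicate 3, 12 without the lens-bearing libraries, 38 with the replicate block and 56 with Xist as a covariate. With only the wild-type groups fitted it was 916, with DESeq2 192, and under inner retina scaling 163. The share that was higher was 83.5%, 94.5% under inner retina scaling and 62.6% when only the wild-type groups were fitted.

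The genes that changed in wild type mostly moved the same way in rd10. Of the 91, 83 (91.2%) had the same sign in rd10 GSK against rd10 saline, and 63 were also called there in that direction. Across these genes the correlation of the changes was 0.84 (Spearman 0.758). This pair of comparisons shares no library, but genes are not independent replicates. In rd10, Hap1 was at 224 ± 11.7 CPM with saline and 370 ± 12.9 with GSK, Baiap3 at 17.4 ± 0.255 and 50.4 ± 7.78, and Zcchc12 at 12.1 ± 0.529 and 29.7 ± 3.18. Of the genes up in wild type 51 were also up in rd10, where independent lists would share 13.4. Of those down 12 were also down in rd10, where 2.29 would be shared. Over all 17099 genes the correlation of the changes in the 2 genotypes was -0.03 (Spearman 0.123), and over the 5646 called in either it was 0.30 (Spearman 0.169). The former includes the lens genes, with medians of -6.88 in wild type and 6.75 in rd10, each set by 1 library. It was not computed without those libraries.

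**Figure D5:**
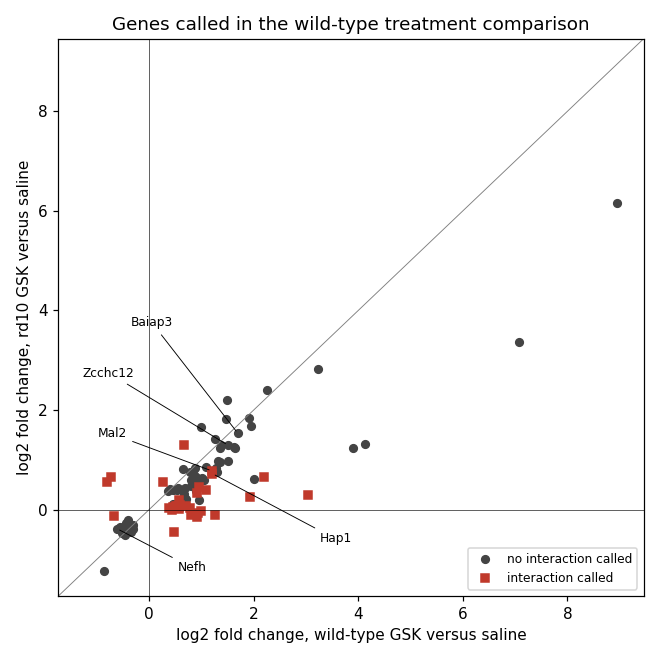
Log2 fold change with GSK in wild type (horizontal axis) and in rd10 (vertical axis) for the 91 genes called in wild type, with squares for the 32 whose interaction was called and a line of equal change. Of the 91 genes 83 have the same sign in both genotypes.

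The change with GSK was larger in rd10 than in wild type for rod genes (n = 3, 3, 3 and 2). For Guca1b the interaction was 2.32 ± 0.20 on the log2 scale (edgeR adjusted p = 0.000140), for Gnat1 2.15 ± 0.30 and for Pde6b 1.94 ± 0.26 (adjusted p = 0.00188). Of 16 rod genes 14 had a higher change (16 adjusted over the list alone, median 1.88), with camera adjusted p = 7.62e-16 (adjusted p = 0.278 with an estimated correlation). Of 24 genes shared by rods and cones 21 did (22 adjusted over the list alone, median 1.40), with adjusted p = 2.20e-20 (adjusted p = 0.247 with an estimated correlation). Immediate-early genes followed (9 of 12, 10 adjusted over the list alone, median 1.40), with adjusted p = 4.44e-07 (adjusted p = 0.247 with an estimated correlation), and the AP-1 subunit Fos was at 1.52 ± 0.25. Of 19 glycolysis genes 6 had a higher and 1 a lower change (9 and 2 adjusted over the list alone, median 0.24, and 0.46 under inner retina scaling), with Hk1 at 0.88 ± 0.09. The glycolysis list had adjusted p = 0.00612 (adjusted p = 0.688 with an estimated correlation and 0.0751 by fry).

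Bipolar genes had a lower change in rd10 than in wild type (9 of 14, 13 adjusted over the list alone, median -0.49, and -0.27 under inner retina scaling), with adjusted p = 2.36e-10 (adjusted p = 0.0085 with an estimated correlation). Müller glia genes did too (6 of 10, 8 adjusted over the list alone, median -0.72), with adjusted p = 1.69e-08 (adjusted p = 0.0085 with an estimated correlation). Examples were Cabp5 (-0.76 ± 0.08), Isl1 (-0.62 ± 0.08), Apoe (-1.61 ± 0.18) and Aqp4 (-1.18 ± 0.12). The cholesterol exporter Abca1 (-1.84 ± 0.19, edgeR adjusted p = 0.000309) and the angiotensinogen gene Agt (-1.75 ± 0.23, adjusted p = 0.000790) lay in the same direction. Microglia genes (6 of 17 lower, 11 adjusted over the list alone, median -1.39) had adjusted p = 7.51e-07 (adjusted p = 0.562 with an estimated correlation), a call that fry does not make. Complement genes (2 of 9 lower, 3 adjusted over the list alone, median -1.15) had adjusted p = 0.0222 (adjusted p = 0.750 with an estimated correlation and 0.387 by fry). Cone genes (4 of 14 lower, 1 higher and 5 lower adjusted over the list alone, median -0.35) had adjusted p = 0.0148 (adjusted p = 0.674 with an estimated correlation and 0.165 by fry). Their median was -0.13 under inner retina scaling and -0.16 without rd10 GSK replicate 1, where the call was lost.

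The next 3 lists passed without any member called over all genes or adjusted over the list alone. Microglial activation had a median of -1.19 and adjusted p = 0.0200 (adjusted p = 0.827 with an estimated correlation and 0.524 by fry). Its median was -2.17 without rd10 GSK replicate 1 and -0.71 without replicate 3, where the call was lost (adjusted p = 0.0646). Interferon response had a median of -1.40 and adjusted p = 0.00612 (adjusted p = 0.827 with an estimated correlation and 0.546 by fry). MHC class I had a median of -1.04 and adjusted p = 0.0164 (adjusted p = 0.750 with an estimated correlation and 0.404 by fry). Without rd10 GSK replicate 3 its median was -0.65. Erythroid genes had a higher change in rd10 (2 of 6, 3 adjusted over the list alone, median 1.08), with adjusted p = 0.00565 (adjusted p = 0.337 with an estimated correlation), a call lost under inner retina scaling. Amacrine (median -0.17, adjusted p = 0.122), ganglion cell (-0.06, adjusted p = 0.506) and reactive gliosis genes (-0.24, adjusted p = 0.645) had no member called over all genes. Camera called the amacrine list without rd10 GSK replicate 3 (adjusted p = 0.0474) and the reactive gliosis list under inner retina scaling (0.0294), pointing down in both. Adjusted over the list alone 1 ganglion cell gene was higher and 1 lower.

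The other 13 lists showed few interactions. Neurotrophic genes had 2 of 17 higher and 1 lower (the same adjusted over the list alone, median 0.17, adjusted p = 0.506). Retinal progenitor (1 of 12, median -0.04, adjusted p = 0.587), pigment epithelium (1 of 12, 0.08, adjusted p = 0.410) and vascular genes (1 of 11, 0.08, adjusted p = 0.829) each had 1 lower, the same adjusted over the list alone. Of the LSD1 and HDAC complexes 1 of 16 was lower (0 adjusted over the list alone, median -0.0019, adjusted p = 0.717), and of 4 horizontal cell genes 1 (2 adjusted over the list alone, median -0.47). Oxidative phosphorylation had 1 of 18 higher (0 adjusted over the list alone, median 0.07, adjusted p = 0.176). Camera called that list without rd10 saline replicate 2 (adjusted p = 0.00145) and under inner retina scaling (0.00150). Under the latter it also called pigment epithelium genes (median 0.34, 0.0104), as it did without the lens-bearing libraries (-0.82, 0.0234), pointing down in both. Cell death (median -0.0050, adjusted p = 0.856), proliferation (-0.30, adjusted p = 0.566), inflammatory mediator (0.43, adjusted p = 0.566), other leukocyte (-0.74) and skeletal muscle genes (2.32) had none called, over all genes or adjusted over the list alone. Inflammatory mediators were called under inner retina scaling with camera pointing down, though their median was 0.69. Over all settings that median ran from -0.43 to 0.95. The lens list had none called over all genes and 12 of 15 higher adjusted over the list alone (median 13.81, adjusted p = 0.154), and turned to -2.06 without the lens-bearing libraries (0.00588). It was also called in 4 settings that kept both, such as the replicate block (4.83e-10) and leaving out wild-type saline replicate 1 (0.000758).

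The interaction was called in 2131 genes, 1280 with a higher and 851 with a lower change in rd10 than in wild type (edgeR QL, BH adjusted p under 0.05). The count was 864 without wild-type saline replicate 1, 960 without replicate 2, and 1280 and 1402 without wild-type GSK replicates 1 and 3. It was 524 without the lens-bearing libraries and 4131 under inner retina scaling (93.9% higher, against 60.1%).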

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

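The tests of the lens and immediate-early patterns were chosen after the results were seen, while the tests of library splits were written before they were run. The difference between genotypes in the response to GSK was tested with the interaction term, which picked out 2131 genes (edgeR QL, BH adjusted p under 0.05). The largest named interactions with a higher change in rd10 were Pdzph1 (3.10), Lad1 (2.87), Ccdc180 (2.44), Sh2d1a (2.37), Guca1b (2.32), Sp6 (2.16), Nrl (2.16), Gnat1 (2.15) and Esrrb (2.14), in log2 units. Those with a lower change were Trim72 (-2.75), Cfi (-2.05), Abca1 (-1.84), C1qc (-1.82), Agt (-1.75), Trem2 (-1.74), Arhgap45 (-1.73), Apoe (-1.61), Tor4a (-1.56) and Gna14 (-1.48). Pdzph1, Guca1b, Sp6, Gnat1, Esrrb, Abca1, Agt and Apoe kept the call in every setting, and the others lost it in at least 1. With 2 or 3 libraries in each group, no library was tested for its distance from its own group, since the rule fixed for this (Dixon's test) was set to groups of 4 to 10. The 3 rd10 GSK libraries lay at 52.0, 23.1 and -10.4 on the first principal component.

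Of the 10 ways to divide the 6 rd10 libraries into sets of 3, only 1, the real one, gave as many as 5621 genes, and the highest of the others gave 0. The 6 GSK libraries divided by genotype gave the same picture, with 1 of 10 divisions reaching 4484 genes and 0 as the highest other. With 10 divisions no share under 0.05 can be reached, so these tests do not by themselves exclude a chance division.

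Lens transcripts stood high in wild-type saline replicate 2 and rd10 GSK replicate 2. An effect of genotype or treatment alone predicts a rise in the other libraries of those groups, and these summed to at most 73.8 CPM. The pair was picked because it stood out, so this is no independent test. It also left out rd10 saline, whose libraries summed to 107, 129 and 106 CPM. The wild-type libraries other than saline replicate 2 summed to between 35.2 and 39.4 CPM, so a smaller genotype difference is not excluded. Lens tissue carried over in dissection predicts a shared profile, and across 15 lens genes, which are not independent replicates, the log2 CPM of the pair correlated at r = 0.959. It also predicted each of 3 lens genes other than crystallins at over 10 times the highest of the other 9 libraries, and Mip reached 3310 times but Bfsp1 5.03 and Bfsp2 9.30 times, so the test as written cannot tell.

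Immediate-early genes were highest in the 3 rd10 GSK libraries, at 580%, 417% and 356% of wild-type saline. GSK acting alike in both genotypes is excluded: the list's median change in wild type was -0.13, while the smallest change in rd10 was 0.38 and 9 of 12 interactions were called. A mixture of wild-type-like and rd10-like retina alone would lie between the saline groups. The lowest rd10 GSK library instead lay 0.69 above the highest saline library in mean log2 CPM. The list was picked for being highest in rd10 GSK, so both comparisons largely restate the pattern and are no independent tests. A handling difference confined to the rd10 GSK mice, such as time from death to freezing, cannot be told apart from a response of rd10 retina to GSK: 0 libraries of the other groups reached that level, and the labels give neither times nor order.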

How the results depend on the processing

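Of 420 named gene results 324 passed the test, 161 of these did so in every setting and 2 turned direction. Of 104 list results 47 passed, 41 of them in every refit, 36 by fry and 4 with an estimated correlation (bipolar and Müller glia, for rd10 GSK against rd10 saline and for the interaction). The limma-voom setting uses the main camera test, which already runs on voom values, so it could not change a list call. DESeq2 had no list test. Of the 57 list results that did not pass, 26 passed in at least 1 refit and 6 by fry. Size factors by relative log expression and the filters on low counts moved no count of calls by over 1.5 times. Replicate numbers do not pair the libraries, and with them as a block the 6 counts, in the order of the comparisons, were 6601, 5404, 38, 1866, 4163 and 3895. Leaving out a wild-type saline library leaves that group with 1 animal, whose spread is then taken from the other groups.

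Genes changed between rd10 saline and wild-type saline numbered 4081 without the 2 lens-bearing libraries, an alternative chosen after seeing the data, and from 4435 to 7506 with 1 library left out. For rd10 GSK against rd10 saline the count was 9073 under inner retina scaling and 3588 with the compared groups only. Inner retina scaling shifts the median of all genes in that comparison by 0.32 and in the interaction by 0.23, so most of the added calls are higher by construction. For wild-type GSK against wild-type saline it was 163 under inner retina scaling, 38 with the replicate block, 56 with Xist as a covariate (also chosen after seeing the data), 12 without the lens-bearing libraries, 916 with the compared groups only, 192 with DESeq2, and from 12 to 182 with 1 library left out. The interaction count was 4131 under inner retina scaling, 524 without the lens-bearing libraries, and from 864 to 3139 with 1 library left out. For rd10 GSK against wild-type GSK it was 2213 without the lens-bearing libraries and from 2515 to 5694 with 1 library left out. For rd10 GSK against wild-type saline it was 7397 under inner retina scaling, 726 without the lens-bearing libraries, 1573 with the compared groups only, and from 1053 to 5319 with 1 library left out. Fewer libraries leave fewer degrees of freedom, which does not account for counts that rose, such as the 916. The fit of all groups shares its dispersions, while the spread within groups was unequal. Chi-square per degree of freedom ran from 32.4 to 49.4 between rd10 GSK libraries. Between wild-type libraries of the same group it ran from 3.72 to 6.94. Beyond this, the cause of the changed counts was not tested.

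Of the genes called without the lens-bearing libraries nearly all had also been called with them: 4000 of 4081, 3686 of 3805, 12 of 12, 509 of 524, 2155 of 2213 and 714 of 726. The correlation of the change with GSK between genotypes was 0.30 over genes called in either and 0.84 over those called in wild type. Without the lens-bearing libraries the lens list turned direction, to a median of 2.15 for rd10 saline against wild-type saline, -0.99 for rd10 GSK against rd10 saline and -2.06 for the interaction, since those libraries held the signal. Camera's direction for that list also turned under inner retina scaling for rd10 GSK against rd10 saline, at a median of 7.07. For inflammatory mediators in the same comparison the median ran from -0.24 with limma-voom to 0.89 under inner retina scaling, and was -0.20 without rd10 GSK replicate 1 and 0.87 without replicate 3, where camera pointed up. Tfap2a (0.10) and Hdac1 (0.058) turned direction under inner retina scaling for rd10 GSK against rd10 saline, and the cause was not tested beyond the shift of the median. For wild-type GSK against wild-type saline 39% of 1.5-fold changes were recovered in simulated data that gave all groups the same dispersions. Small responses there are mostly out of reach of the fit of all groups. That limit is not set by depth and group size alone, since fitting only the wild-type groups called 916 genes in place of 91.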

Other observations

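The set of genes below was defined after the results were seen, and the tests of their positions were written before they were run. These genes differed in 1 direction between rd10 saline and wild-type saline and between rd10 GSK and each wild-type group. Their log2 difference was at least 0.5 with saline, and with GSK at least 0.8 times as large. For the same linear return this rule is met more easily by higher genes, so the sizes of the 2 sets were not compared. Among 675 that stayed higher were the metallothionein Mt2, at 14.2 ± 2.38 CPM in wild-type saline, 15.2 ± 3.06 in wild-type GSK, 124 ± 19.2 in rd10 saline and 149 ± 33.2 in rd10 GSK, and its relative Mt1. The photoreceptor survival factor Fgf2, whose log2 difference from wild-type saline was 2.54 with saline and 3.47 with GSK, was at 5.39 ± 0.385, 4.99 ± 0.0925, 31.4 ± 9.48 and 59.8 ± 26.0 CPM, with no call between the rd10 groups (0.93 ± 0.33, edgeR adjusted p = 0.0639), though all 3 rd10 GSK libraries lay above wild type. The receptor gene Notch1 (1.60 ± 0.18 for rd10 GSK against wild-type saline) and the progenitor factor Sox2 (0.64 ± 0.10) stayed higher as well. Among 61 that stayed lower were Sun2 and the potassium channel subunit Kcne2, at 101 ± 6.64, 106 ± 6.75, 47.9 ± 7.71 and 54.2 ± 15.1 CPM.

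Genes that stay lower whatever the treatment could mark stretches of donor-strain sequence that came with the rd10 allele, rather than a response of the retina. If so, members should lie next to each other in gene order (RefSeq, GRCm38), and 51 of the 61 could be placed. Of these 4 had another member within 5 tested genes, against a median of 2 and a 95th percentile of 6 in 1000 random sets matched on expression (one-sided permutation p = 0.254), so the test cannot tell. None, 0 of the 100 tested genes nearest to Pde6b, belonged to the set, which excludes a segment of that size as the source of the whole set, but with 0.321 expected it cannot show that the region is spared. For the 651 placed genes of the higher set 294 had such a neighbour, against a median of 199 and a 95th percentile of 225 (permutation p = 0.001, the smallest that 1000 draws allow), as gene families induced together also would.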
